A study of Mus musculus with 33 samples.

How the data were processed

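RNA sequencing counts of the mouse frontal bone region were analysed for 33 libraries, 3 at each of 11 stages from E8.5 to E14.5. The deposited table holds raw counts per gene, whole numbers that were not normalized, with replicates kept as separate columns, per the file headers and the values. The authors' notes name cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1 and the genome build GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping antisense genes, and of near-identical copies such as globin and osteocalcin genes or ribosomal protein genes with processed copies, may therefore not be told apart. The deposited table also gives the exonic length of each gene, per the file headers, which served only the correction for gene length. Columns were tied to stages by their names. The letters a, b and c that end the column names could not be tied to the replicate numbers of the labels and serve here as names only.

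Of 55401 genes in the table, 55141 had a symbol in the GENCODE M21 annotation and 260 did not and were kept under their identifiers. Column totals ran from 14516518 to 19964404, and between 99.86% and 99.96% of counts lay in tested genes. A count of 0 over a group was treated as a level below 3 counts over the group, and fold changes against such a group are bounds that cover counting error only. No pair of libraries within a stage had identical counts, and none agreed within sampling noise. A chi-square statistic per gene, over genes with at least 20 counts in the pair, was 1.85 or more in every such pair.

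Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter given the stages (20073 genes), and libraries were scaled with TMM factors (0.797 to 1.175). A quasi-likelihood model with a mean per stage was fitted to all 33 libraries, with 22 residual degrees of freedom. An F-test asked for any change over the 11 stages. Contrasts compared E14.5 with E8.5, E10.5 with E8.5, E12.5 with E10.5 and E14.5 with E12.5, and each stage with the one before it. A gene passed with a Benjamini-Hochberg adjusted p below 0.05. Standard errors of log2 fold changes were computed from the fold change and its F statistic and are approximate, above all where a stage has few counts. Log2 CPM used a prior count of 2.

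The design, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. There were 40 gene lists for bone, matrix, metabolism, signalling, cell state and other tissues, with 516 member entries tested. Camera (limma 3.58.1) compared each list with the other genes at a preset correlation of 0.01, over 160 tests of lists by contrasts adjusted together. Of 84 calls, 49 held with an estimated correlation, and where a call described in the text was lost, that p stands beside it. Fry tested whether members moved, on balance, one way, without comparing them with other genes, and is given for the citrate and vesicle lists.

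The rule named, in each of the 4 main contrasts, the 6 largest rises and 6 largest falls that passed with a mean of at least 5 CPM in the higher stage and no overlap between replicates, and in each step the largest rise and the largest fall. It left out predicted genes, clones and pseudogenes. For a list described, it took the 4 passing members with the largest change, or all members of a list of at most 4. The citrate genes and Runx2, Sp7, Alpl, Spp1, Ibsp, Bglap, Dmp1 and Phex were always included. A few genes that the rule takes are not reported here.

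The method was tested on simulated data with each gene's mean over all libraries, the real spread and the real library sizes. In these data, 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold at E14.5. The contrast of E14.5 with E8.5, on 19160 genes, recovered 34.3%, 65.7% and 81.8% of them, with 9 false calls. Camera called the changed list and 0 of 40 unchanged lists. Genes were drawn independently of each other, so this does not test camera on lists whose members are correlated. Few genes were changed, so scaling was not tested for contrasts in which most genes change.

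The first set of alternatives held DESeq2's size factors, scaling by totals alone, no filter, a stricter filter, DESeq2 1.42.0, a block on the column letter, a fit of only the libraries compared, and each library left out in turn. Chosen after seeing the data were a correction for gene length in each library, a fit without the E11.5, E12 and E13.5 libraries, and the libraries labelled E11.5 in place of those labelled E12.5. Other splits of the libraries into groups of the same sizes were tested for each count of genes. Figures were drawn with matplotlib 3.10.9.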

Results

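The series followed gene expression in the frontal bone region of the mouse skull vault, a flat bone that forms by direct ossification of mesenchyme, over 11 stages of embryonic development. Sampling began at E8.5, E9, E9.5 and E10, went on through E10.5, E11, E11.5 and E12, and ended with E12.5, E13.5 and E14.5. There were 3 libraries at each stage, 33 in all. Each library was a column of raw read counts for 55401 genes, and column totals ran from 14516518 to 19964404 counts with a median of 17081223. After a filter on low counts, 20073 genes were tested. Levels are CPM (read counts scaled to a common library size and corrected for library composition), given as mean ± SD over n = 3 libraries. Log2 fold changes are given ± an approximate standard error, computed from the fold change and its F statistic in edgeR's quasi-likelihood fit. Where a stage has few counts, this value can lie below the counting error. P-values are Benjamini-Hochberg adjusted. The labels do not say whether the 3 libraries of a stage came from separate embryos, separate pools or a single preparation, so the p-values measure only the spread between these libraries. The series title names citrate, its transport by extracellular vesicles and biomineralization, and the comparisons follow genes of these processes and of the tissues around them over time.

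Of the 20073 genes, 19136 (95.3%) differed between stages in a test of any change. Mean expression was highest at E14.5 for 20.2% of these genes, at E12 for 19.2%, at E8.5 for 12.3% and at E11.5 for 11%. The first principal component of log2 CPM held 47.1% of the variance and ran from -123.4 at E8.5 to 109.7 at E14.5, but the stages did not all lie in labelled order along it. The libraries labelled E11.5 had a mean of 84.1, above those labelled E12 (22.1) and E12.5 (41.9). Those labelled E11 (34.6) also lay above E12, and those labelled E10 (-37.9) lay above E10.5 (-46.4). The E10.5 libraries are an end of the contrasts with E8.5 and with E12.5. At 9 stages, pairs of libraries correlated across genes at 0.9879 to 0.9909 in log2 CPM, against 0.9649 to 0.9856 at E12, while at E13.5 the lowest pair stood at 0.9749. Genes of cytosolic ribosomal proteins took 6.25% ± 2.12 of the counts at E12, and 2.40% ± 0.03 and 2.94% ± 0.11 at E11.5 and E12.5. Globin genes took 1.85% ± 0.68 at E12, against 0.29% ± 0.01 and 0.46% ± 0.03 at those stages. Hbb-bh1 and Hbb-y, 2 globins of embryonic red cells, stood in a ratio of 0.979 ± 0.018 at E8.5, 0.54 ± 0.019 at E10.5 and 0.0075 ± 0.00046 at E14.5. That ratio was 0.0135 ± 0.00083 at E11.5 and higher at E12 and E12.5, at 0.0688 ± 0.01 and 0.058 ± 0.0053. These globin genes were chosen after their values were seen.

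**Figure D1:**
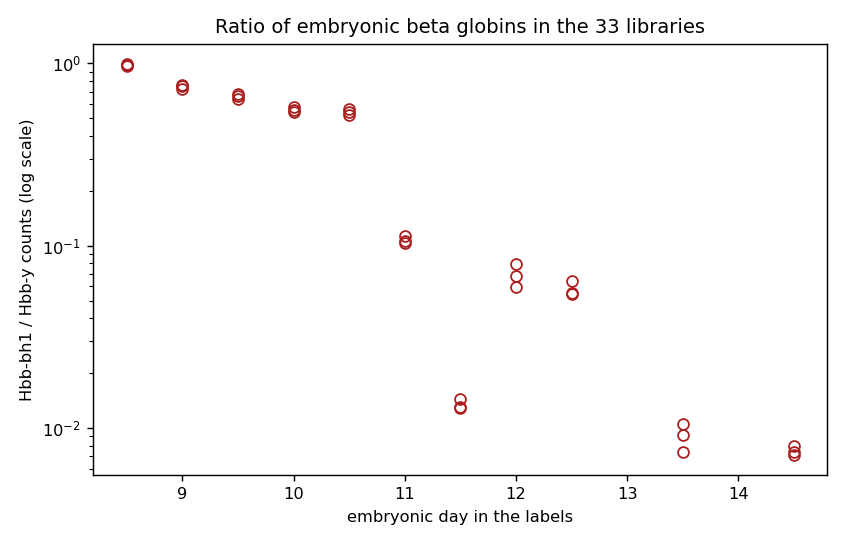
Ratio of Hbb-bh1 to Hbb-y counts (vertical axis, log scale) against the embryonic day in the labels (horizontal axis), with a circle for each of the 33 libraries. The 3 libraries labelled E11.5 lay at 0.0129 to 0.0144, below all 6 libraries labelled E12 and E12.5, of which the lowest was at 0.0545.

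**Figure D2:**
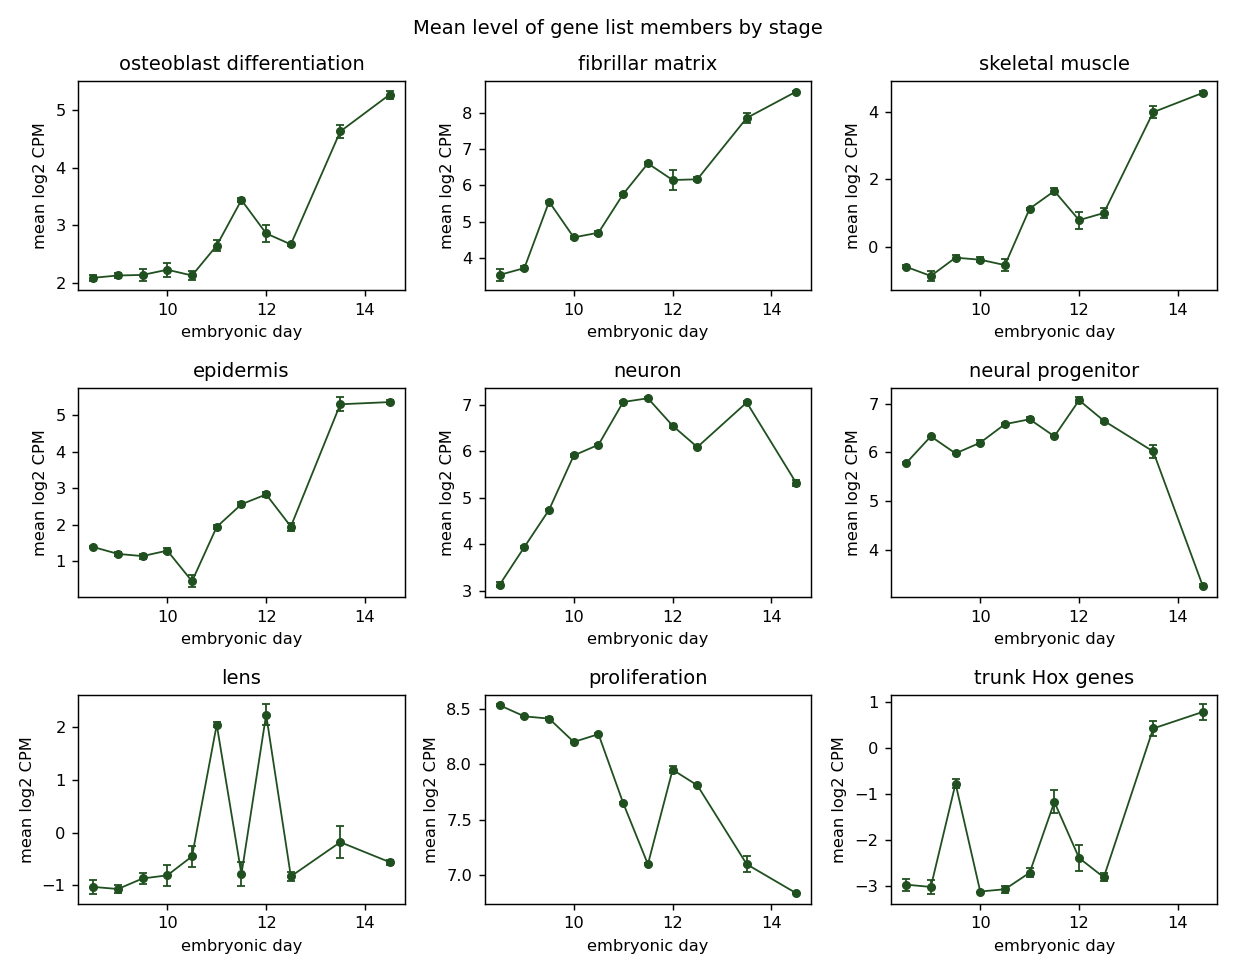
Mean log2 CPM of the members of 9 gene lists (vertical axes) against embryonic day (horizontal axes), with points for the mean and bars for the SD of 3 libraries. The osteoblast list stood at 2.09 at E8.5, 3.44 at E11.5, 2.67 at E12.5 and 5.27 at E14.5, and the lens list was at 2.05 at E11, -0.79 at E11.5 and 2.24 at E12.

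Between the ends of the course, E8.5 and E14.5, genes of bone, cartilage, fibrillar matrix, muscle, neurons, macrophages and epidermis rose, and genes of early embryonic cells, neural progenitors, cell division and glycolysis and non-globin erythroid genes fell. Bone sialoprotein Ibsp, a mineral-binding matrix protein of osteoblasts, rose from 0.278 ± 0.18 to 464 ± 14 CPM (log2 fold change 10.63 ± 0.29, adjusted p = 4.16e-21). Of the 18 measured genes on the osteoblast list, 13 rose, 1 fell and 4 did not pass (camera adjusted p = 0.00013). Col1a1, which encodes the main collagen chain of bone, rose by 6.70 ± 0.20 on the log2 scale to 1882 ± 120 CPM. Runx2, the transcription factor that commits cells to the osteoblast lineage, rose from 0.576 ± 0.12 to 45.1 ± 3.1 CPM. Dmp1, an acidic matrix phosphoprotein of osteocytes, had no count at E8.5 and 1.61 ± 0.65 CPM at E14.5, at least 24.3-fold higher against a floor of 3 counts over the group. The member that fell was the stress response factor Atf4, by 0.84 ± 0.13 on the log2 scale, and those that did not pass included Alpl, Bglap and Dlx3. Here and in the other lists, members that went against the rest or did not pass are named after their values were seen.

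Of 24 fibrillar matrix genes 23 rose and none fell (camera adjusted p = 9.38e-14). The small leucine-rich proteoglycans asporin (Aspn), osteoglycin (Ogn) and decorin (Dcn) reached 131 ± 16, 227 ± 19 and 516 ± 36 CPM, from 0.165 ± 0.18, 0.573 ± 0.39 and 1.34 ± 0.29, and Col6a3 rose by 7.74 ± 0.28 on the log2 scale. All 16 measured skeletal muscle genes were higher at E14.5 (camera adjusted p = 4.8e-07). Among them were the embryonic myosin Myh3 (166 ± 14 CPM) and the myogenic factor Myog, with no count at E8.5 and at least 340-fold higher, along with Myh8 and Tnnc2, which rose by 8.32 ± 0.28 and 7.96 ± 0.67. Of 12 macrophage genes 11 rose (camera adjusted p = 8.18e-07), led by Tyrobp, at least 259-fold higher, and the complement genes C1qa, at least 207-fold higher, C1qb (29.8 ± 3.6 CPM) and C1qc (26.0 ± 1.7 CPM). Of 14 epidermal genes 13 rose (camera adjusted p = 2e-05), with the basal keratins Krt5 and Krt14 at 483 ± 44 and 341 ± 20 CPM, Krt15 at 168 ± 21 and the late keratinocyte gene Krtdap at 9.64 ± 1.6. The members of these lists that did not pass were Fbn2, Cd68 and Lor. Beside bone and matrix, 12 of 17 cartilage genes rose, Matn1 and Acan by 8.23 ± 0.34 and 5.10 ± 0.23, and Sox9 and Col2a1 fell (camera adjusted p = 0.00308). Of 15 neuronal genes 14 rose and Neurog2 fell by 1.66 ± 0.23 (camera adjusted p = 4.65e-06).

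Lin28a, an RNA-binding protein that blocks let-7 maturation, fell from 964 ± 7.5 to 0.568 ± 0.30 CPM, and Sall4, a factor of pluripotent cells, fell from 128 ± 5.1 to 0.171 ± 0.14. Lin28b fell by 5.65 ± 0.11 and the DNA methyltransferase Dnmt3b fell by 3.31 ± 0.13 on the log2 scale. Of the 6 genes of this early list 4 fell, L1td1 rose by 0.67 ± 0.24 and Nanog did not pass (camera adjusted p = 0.00437). Of 20 proliferation genes 19 fell (camera adjusted p = 2.64e-11), Mki67 not passing. Rrm2, a subunit of ribonucleotide reductase, fell from 489 ± 7.0 to 55 ± 3.1 CPM, and Mcm7, Plk1 and Mcm2 fell by 2.49 ± 0.08, 2.44 ± 0.07 and 2.29 ± 0.13. Among 18 glycolysis genes 15 fell and Pfkp alone rose, by 1.04 ± 0.15 (camera adjusted p = 1.32e-07). The lactate exporter Slc16a3 fell from 312 ± 9.5 to 23.7 ± 2.8 CPM, and Hk2, Slc2a3 and Pfkl fell by 3.13 ± 0.12, 2.81 ± 0.09 and 2.79 ± 0.11. Of 22 genes of the TCA cycle 17 fell and none rose, and Dlat, Cs, Pdha1 and Suclg2 fell by 1.33 ± 0.09, 1.28 ± 0.07, 1.18 ± 0.06 and 1.15 ± 0.09. That list's camera adjusted p was 0.000187 with the preset correlation and the adjusted p = 0.113 with an estimated correlation. Of 34 oxidative phosphorylation genes 19 fell, 18 adjusted over the list alone (camera adjusted p = 0.00616, and adjusted p = 0.664 with an estimated correlation). Beside these falls, 11 of 13 genes of the mitochondrial genome rose, mt-Co3 and mt-Nd5 by 1.84 ± 0.23 and 1.75 ± 0.15 (camera adjusted p = 0.028, and adjusted p = 0.389 with an estimated correlation). Of 35 ribosomal protein genes 33 fell, 34 adjusted over the list alone (camera adjusted p = 1.44e-05, and adjusted p = 0.494 with an estimated correlation). Markers of other cells moved with these falls. Of 12 neural progenitor genes 10 fell, Sox3, Sox1 and Sox2 by 6.53 ± 0.20, 6.26 ± 0.14 and 3.24 ± 0.09, and Fabp7 and Emx2 rose (camera adjusted p = 4.01e-06). Of 9 non-globin erythroid genes 8 fell, Hemgn and Gata1 by 4.58 ± 0.24 and 2.96 ± 0.24, and Alas2 rose by 0.30 ± 0.11 (camera adjusted p = 0.000867). With the length trend removed, 1 neural progenitor gene and 0 erythroid genes were higher. The definitive globins Hbb-bt, Hbb-bs, Hba-a2 and Hba-a1 all rose, by 7.89 ± 0.38, 7.52 ± 0.33, 3.26 ± 0.42 and 2.15 ± 0.26 (camera adjusted p = 0.0108, and adjusted p = 0.262 with an estimated correlation). All 11 immediate early and heat shock genes, which also respond to handling of tissue, were lower at E14.5 than at E8.5 (camera adjusted p = 0.000262).

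By size alone, the 6 largest rises that met the naming rule were Tnmd (tenomodulin, of tendon), Fstl5, Olfm5, Kcne4, Cpa3 (a mast cell protease) and Epyc (epiphycan, of cartilage). None had a count at E8.5, and they were at least 768, 581, 512, 490, 459 and 351-fold higher at E14.5. The 6 largest falls began with Msx3, a homeobox gene of the dorsal neural tube, at least 412-fold lower, and went on with Lin28a, Nkx2-9, Pax8, Sall4 and Pax5. Nkx2-9 went from 20.7 ± 2.8 to 0.0178 ± 0.031 CPM, Pax8 from 18.0 ± 2.0 to 0.0153 ± 0.026 and Pax5 from 97.0 ± 12 to 0.137 ± 0.067. In every gene named by size, the 3 libraries of one stage all lay above the 3 of the other, because the naming rule required it. In all, 8243 genes were higher and 6731 lower, 6055 and 3256 of them by at least 2-fold. Adjusted over the list alone, the counts for the osteoblast list were 14 higher and 1 lower and those for glycolysis 2 and 15. Apart from these and from oxidative phosphorylation and ribosomal proteins, the lists described for these stages gave the same counts. Rises made up 55% of the calls, 71.3% (10617 higher, 4265 lower) when libraries were scaled to their totals alone, which shifted the median of all genes by 0.43 on the log2 scale, and 46.1% with a gene length trend removed, which shifted it by -0.25. The length correction was chosen after seeing the data.

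The citrate list held 11 measured genes, and all 11 differed across the stages. At E14.5 against E8.5, 3 were higher, 5 lower and 3 did not pass, with the same counts when adjusted over the list alone. Slc13a5 (ENSMUSG00000020805, GRCm38 chromosome 11, 72241989 to 72267222, minus strand), a plasma membrane importer of citrate, stood at 0.20 ± 0.21 CPM at E8.5, on 9 counts, and 16.2 ± 0.38 at E14.5, on 962 counts. Its log2 fold change was 6.30 ± 0.40 (adjusted p = 9.35e-15). Its level was 1.05 ± 0.24 CPM at E10, 0.317 ± 0.13 at E11, 1.16 ± 0.32 in the libraries labelled E11.5, 0.205 ± 0.043 at E12, 0.221 ± 0.099 at E12.5 and 2.49 ± 0.79 at E13.5. The differences into and out of E11.5 were 1.84 (adjusted p = 0.00221) and -2.45 (adjusted p = 0.000111). The related carboxylate importer Slc13a3 rose by 3.04 ± 0.45 (adjusted p = 6.16e-07), with its highest mean at E13.5, 3.44 ± 0.51 CPM, and Slc13a2 was not tested, having 4 counts in all libraries together. Citrate synthase Cs fell from 352 ± 7.9 to 144 ± 7.0 CPM, ATP citrate lyase Acly from 654 ± 5.8 to 219 ± 16, and the mitochondrial citrate carrier Slc25a1 from 78.1 ± 2.8 to 30.9 ± 0.60 (log2 fold change -1.34 ± 0.13, adjusted p = 1.77e-10). The cytosolic aconitase Aco1 fell by 0.83 ± 0.08, and Idh1, the cytosolic isocitrate dehydrogenase, rose by 0.66 ± 0.08. Idh2, Ank, which exports pyrophosphate and citrate, and the zinc transporter Slc39a1 had log2 differences of 0.13 ± 0.10, -0.16 ± 0.09 and 0.17 ± 0.08 and did not pass.

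As a list these genes were not shown to move relative to other genes (camera adjusted p = 0.446, direction down), with a median log2 change of -0.16, which was 0.27 with totals alone, and a mean of 0.41. Fry, which does not compare a list with other genes, put the members on balance lower (adjusted p = 4.35e-07), against the sign of the mean. With totals alone, Idh2 at 0.57 (adjusted p = 1.66e-06), Slc39a1 at 0.60 (adjusted p = 1.14e-07) and Ank at 0.27 (adjusted p = 0.0172) passed. Ank also passed without E14.5 replicate a (-0.23, adjusted p = 0.0351) and Slc39a1 without E8.5 replicate b (0.20, adjusted p = 0.0363) or with DESeq2 (adjusted p = 0.00302). Idh2 and Slc39a1 also passed with only the 6 libraries compared (0.15, adjusted p = 0.0167, and 0.18, adjusted p = 0.00732), and Ank with the length trend removed (-0.41, adjusted p = 9.46e-05). Of 27 genes of extracellular vesicle biogenesis, 13 rose, 11 fell and 3 did not pass (camera adjusted p = 0.548), with the same counts when adjusted over the list alone, and fry put them on balance higher (adjusted p = 1.81e-09).

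**Figure D3:**
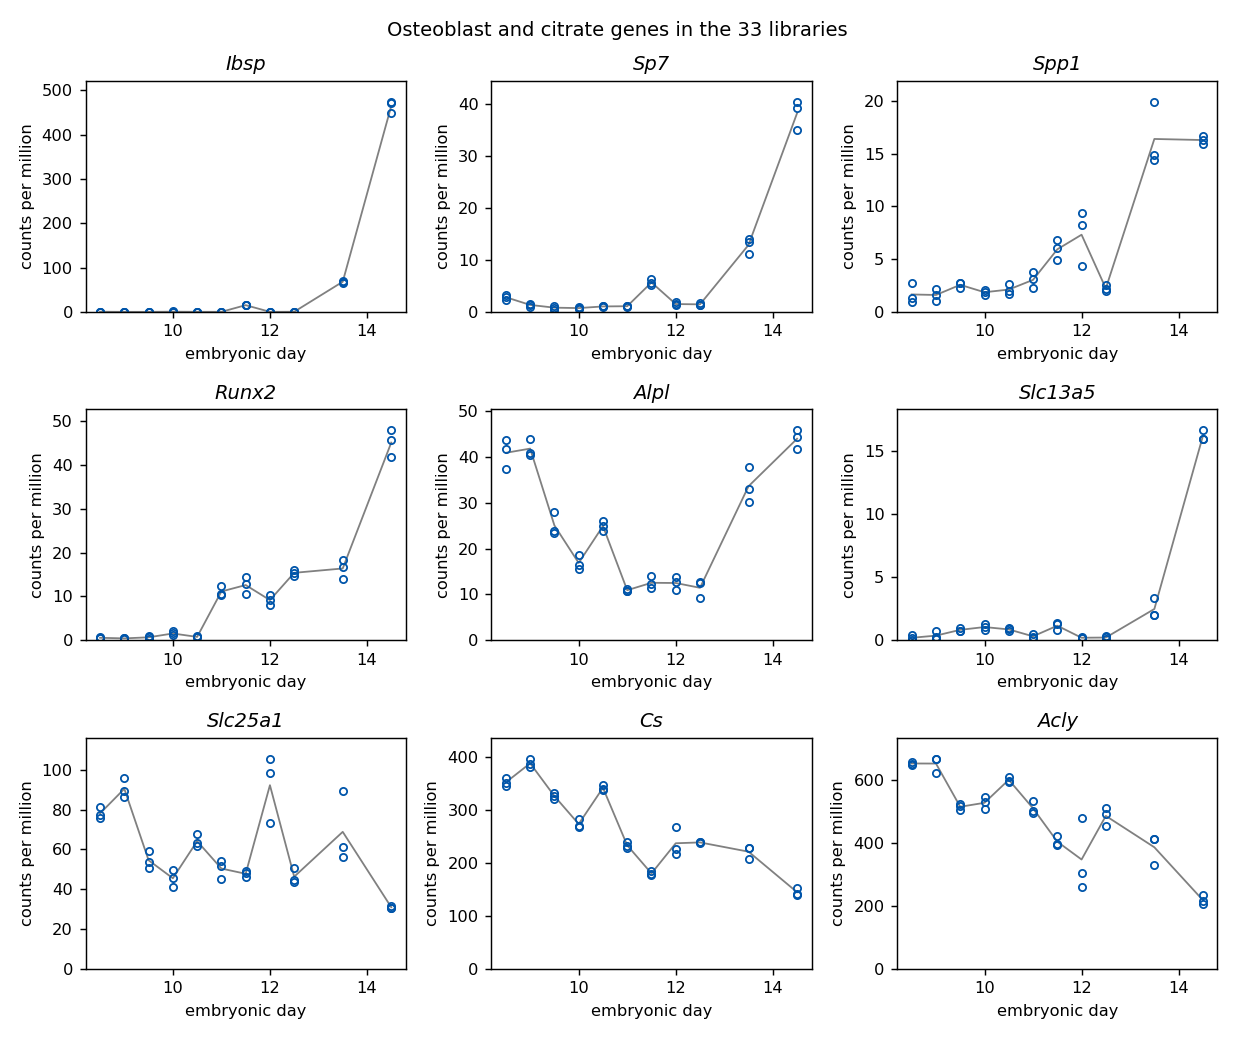
CPM (vertical axes, linear from 0) of 5 bone genes and 4 citrate genes against embryonic day (horizontal axes), with open circles for the 33 libraries and lines through the stage means. Ibsp, Sp7 and Slc13a5 were highest at E14.5, at 464, 38.2 and 16.2 CPM, whereas Cs and Acly were lowest there, at 144 and 219.

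The bone genes followed in every library had different courses. Ibsp (ENSMUSG00000029306, GRCm38 chromosome 5, 104299171 to 104311469) stood at 15.1 ± 0.63 CPM in the libraries labelled E11.5, 0.037 ± 0.064 at E12, 0.204 ± 0.078 at E12.5 and 67.9 ± 2.7 at E13.5. Sp7, or osterix, a transcription factor acting after Runx2, was at 5.65 ± 0.55 in the libraries labelled E11.5, 1.44 ± 0.19 at E12.5 and 38.2 ± 2.8 at E14.5. Runx2 was at 11.1 ± 1.2 CPM at E11, 12.6 ± 1.9 in the libraries labelled E11.5, 9.17 ± 1.2 at E12 and 15.4 ± 0.67 at E12.5, so that it did not share the order of Ibsp and Sp7 at E11.5 and E12.5. Alpl, the tissue-nonspecific alkaline phosphatase that frees phosphate for mineral, was at 40.9 ± 3.3 at E8.5, 11.4 ± 1.9 at E12.5 and 43.9 ± 2.0 at E14.5. Its difference between the ends did not pass (0.11 ± 0.11, adjusted p = 0.375), but did with totals alone (0.54, adjusted p = 3.89e-05). Osteopontin Spp1 rose by 3.31 ± 0.28 and Phex, an enzyme of phosphate balance, by 4.18 ± 0.37 between the ends. Osteocalcin Bglap did not pass the test of any change (adjusted p = 0.146), with 0.346 ± 0.15 CPM at E14.5, and near-identical neighbouring copies can share its reads. Of 14 phosphate and mineralization regulators, 10 rose, the phosphate transporters Slc20a1 and Slc20a2 fell by 0.90 ± 0.07 and 1.08 ± 0.09, and 2 did not pass, with the same counts when adjusted over the list alone. Mgp, an inhibitor of calcification, rose by 8.78 ± 0.37 along with Ibsp, Dmp1 and Phex (camera adjusted p = 0.0266, and adjusted p = 0.146 with an estimated correlation).

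Over the early window, E8.5 to E10.5, genes of neurons and macrophages rose and genes of glycolysis, ribosomal proteins and the immediate early response fell. All 15 neuronal genes rose (camera adjusted p = 7.53e-17), including doublecortin Dcx from 1.84 ± 0.39 to 120 ± 7.3 CPM and the RNA-binding protein Elavl3 from 8.35 ± 0.36 to 128 ± 1.6, with Neurog2 and Stmn3 up by 3.45 ± 0.18 and 3.24 ± 0.24. Of 12 neural progenitor genes 8 rose, Six3 fell by 0.63 ± 0.10 and 3 did not pass (camera adjusted p = 0.00437). Fabp7, Hes5, Nes and Emx2 rose by 3.24 ± 0.18, 2.49 ± 0.17, 1.99 ± 0.07 and 0.95 ± 0.09. Of 12 macrophage genes 11 rose, all but Cd68 (camera adjusted p = 1.56e-09). The fractalkine receptor Cx3cr1 went from 0.0234 ± 0.041 to 8.77 ± 0.34 CPM, C1qb from 0.0195 ± 0.034 to 7.84 ± 0.42, and Tyrobp and C1qa, with no count at E8.5, were at least 50.1-fold and 35.2-fold higher. Other rises among the 6 largest were those of Slc17a6, a vesicular glutamate transporter of neurons (13.9 ± 1.4 CPM at E10.5), Actl6b (7.53 ± 1.5), C1qc (5.46 ± 0.65) and Bcl11a (28.0 ± 2.5).

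All 11 immediate early and heat shock genes were lower at E10.5 than at E8.5 (camera adjusted p = 3.16e-10). The AP-1 genes Fosb and Fos stood at 42.9 ± 2.7 and 27.8 ± 1.1 CPM at E8.5 and at 0.0716 ± 0.062 and 0.494 ± 0.13 at E10.5, and Egr1 and Hspa1a fell by 4.53 ± 0.18 and 3.07 ± 0.37 on the log2 scale. Egr1 was at 61.7 ± 2.8 CPM at E8.5 and 2.06 ± 0.40 at E9. Of 18 glycolysis genes 15 fell and Hk1, Pfkm and Pfkp rose by 0.53 ± 0.13, 0.25 ± 0.08 and 0.47 ± 0.15 (camera adjusted p = 6.41e-10). The mean log2 CPM of the glycolysis list was 8.76 at E8.5, 9.06 at E9 and 7.66 at E10.5. The glucose transporter Slc2a3 fell from 834 ± 8.6 to 69.4 ± 2.4 CPM, and Slc16a3, the lactate dehydrogenase Ldha and the kinase Pgk1 fell by 1.98 ± 0.10, 1.63 ± 0.12 and 1.53 ± 0.16. All 35 ribosomal protein genes fell, and Rps6, Rpl27, Rps23 and Rpl13 fell by 1.27 ± 0.16, 1.23 ± 0.14, 1.09 ± 0.16 and 1.08 ± 0.22. The call for that list (camera adjusted p = 3.16e-10) was lost, at adjusted p = 0.301 with an estimated correlation, and many of these genes have processed copies that can share reads. The other large falls were Eras (7.11 ± 0.82 to 0.0872 ± 0.058 CPM), a Ras gene of embryonic stem cells, Car4 (147 ± 3.6 to 4.60 ± 0.57), Foxi2 (18.2 ± 1.9 to 0.595 ± 0.20) and the imprinted gene Phlda2 (5.23 ± 0.17 to 0.178 ± 0.065).

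Of the 18 osteoblast genes in the early window, Col1a1, Col1a2, Dmp1, Pth1r and Sparc rose, Alpl, Atf4, Dlx3, Dlx5 and Sp7 fell and 8 did not pass (camera adjusted p = 0.689). Sp7 fell by 1.44 ± 0.23 and Dlx3 fell by 3.04 ± 0.20. Within the citrate list, Slc13a5, Slc13a3 and Idh1 rose by 2.08 ± 0.53, 2.21 ± 0.49 and 1.06 ± 0.08, and the other 8 did not pass (camera adjusted p = 0.736), with a median of -0.04 and a mean of 0.44, and fry put the list on balance higher (adjusted p = 0.000254). Slc25a1, at -0.28 ± 0.13 (adjusted p = 0.0625), passed without E8.5 replicate a (-0.34, adjusted p = 0.0465) and with DESeq2 (-0.34, adjusted p = 0.0196). With only the 6 libraries compared Acly (-0.15, adjusted p = 0.000346) and Aco1 (-0.16, adjusted p = 0.00174) passed, and with the length trend removed they did too, as did Cs (-0.23, adjusted p = 0.000547) and Ank (-0.25, adjusted p = 0.0177). Slc39a1 and Idh2 passed with totals alone (0.33, adjusted p = 0.00102, and 0.21, adjusted p = 0.0496). Adjusted over the list alone, 6 osteoblast genes were higher and 5 lower, and the other lists described for this window gave the same counts. In total 5666 genes were higher and 4272 lower (57% higher), against 7190 and 2728 (72.5%) with totals alone and 4565 and 6393 (41.7%) with the length trend removed, which shifted the median by 0.18 and -0.16.

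Over the middle window, E10.5 to E12.5, matrix and muscle genes rose, and non-globin erythroid genes, hedgehog targets and proliferation genes fell. Of 24 fibrillar matrix genes 18 rose and Fbn2 fell by 0.66 ± 0.20 (camera adjusted p = 1.7e-13), with Aspn, Ogn and Dcn at 6.01 ± 2.2, 38.3 ± 6.9 and 56.3 ± 2.7 CPM and periostin (Postn) at 82.8 ± 3.4. Of 16 skeletal muscle genes 11 rose and Des and Myf5 fell by 1.24 ± 0.26 and 1.28 ± 0.45 (camera adjusted p = 7.83e-05). Myh8, with no count at E10.5, was at least 36.6-fold higher, Myog reached 1.93 ± 0.45 CPM, and Myod1 and Tnnc2 rose by 3.75 ± 0.81 and 3.59 ± 0.87. Among 18 osteoblast genes 7 rose and Alpl and Pth1r fell, by 1.12 ± 0.11 and 0.57 ± 0.12. Runx2 rose from 0.779 ± 0.11 to 15.4 ± 0.67 CPM, and Omd, Dlx3 and Dlx5 rose by 3.72 ± 0.95, 1.40 ± 0.23 and 1.25 ± 0.17. The list's camera adjusted p was 0.0407, the adjusted p = 0.12 with an estimated correlation, and leaving out E10.5 replicate b gave 0.0508. In the citrate list none rose, and Slc13a5, Cs, Slc25a1 and Aco1 fell by 1.92 ± 0.50, 0.52 ± 0.07, 0.47 ± 0.13 and 0.24 ± 0.08 (camera adjusted p = 0.0266, and adjusted p = 0.0668 with an estimated correlation, fry adjusted p = 6.16e-07).

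All 9 non-globin erythroid genes fell in that window (camera adjusted p = 5.75e-09), Hemgn from 20.6 ± 0.36 to 1.94 ± 0.57 CPM, and Gata1 and Klf1 fell by 2.59 ± 0.21 and 1.87 ± 0.20. Of the 4 definitive globins Hbb-bs, Hbb-bt and Hba-a2 rose by 4.31 ± 0.29, 2.21 ± 0.28 and 1.08 ± 0.38 and Hba-a1 did not pass (camera adjusted p = 0.0108, and adjusted p = 0.262 with an estimated correlation). Of the 3 primitive globins Hbb-bh1 and Hba-x fell by 3.17 ± 0.17 and 1.93 ± 0.18 and Hbb-y did not pass (camera adjusted p = 0.00626, and adjusted p = 0.175 with an estimated correlation). The 4 hedgehog feedback targets all fell (camera adjusted p = 4.5e-06). Ptch1 went from 223 ± 7.2 to 55.1 ± 2.8 CPM, and Hhip and Gli1 fell by 1.96 ± 0.21 and 1.31 ± 0.12. Of 20 proliferation genes 16 fell (camera adjusted p = 2.13e-09), and Rrm2, Plk1, Mcm4 and Mcm2 fell by 1.03 ± 0.06, 0.82 ± 0.07, 0.72 ± 0.06 and 0.64 ± 0.12. The largest single rises were Ttr, a thyroid hormone carrier made by choroid plexus (180 ± 6.9 CPM from 0.0343 ± 0.030), the cortical neuron factors Neurod6 (39.7 ± 3.5) and Neurod2 (46.9 ± 4.6), Aspn, Epyc (8.42 ± 1.9) and Krt5 (23.4 ± 3.2). Among the largest falls, Foxa2 of the ventral neural tube, Wnt1 of the midbrain and the lens factor Foxe3 had no count at E12.5 and were at least 329, 205 and 97.8-fold lower. En2 went from 64.2 ± 2.6 to 0.0692 ± 0.12 CPM, and Nkx2-4 and Nkx2-9 ended at 0.0198 ± 0.034 and 0.116 ± 0.16. Adjusted over the list alone, 20 fibrillar matrix genes, 12 muscle genes and 0 citrate genes were higher and 1, 2 and 5 lower, and the other lists described for this window gave the same counts.

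In total 3765 genes were higher and 3444 lower at E12.5 than at E10.5, 52.2% higher, against 68.4% with totals alone (4783 and 2211), which shifted the median by 0.12. When the libraries labelled E11.5 took the place of those labelled E12.5, an exchange chosen after seeing the data, 5595 genes were lower than at E10.5, the Slc13a5 difference was 0.42 (adjusted p = 0.344) and Ibsp was higher by 7.31 (adjusted p = 9.89e-15). Acly, at -0.31 ± 0.12 (adjusted p = 0.0543), passed with no filter (0.0147), with only the 6 libraries compared (0.000221), with the length trend removed (0.00996), without the E11.5, E12 and E13.5 libraries (1.59e-06) and with E11.5 in place of E12.5 (-0.57, adjusted p = 0.000272), and had its highest adjusted p with totals alone (0.384). The Aco1 call was lost with totals alone (adjusted p = 0.449), with no filter (0.142) and without E12.5 replicate b (0.124), E10.5 replicate b (0.0584) or E10.5 replicate c (0.0663).

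Over the late window, E12.5 to E14.5, genes of bone, matrix, cartilage, muscle and epidermis rose, and neural progenitor and proliferation genes fell. Of 18 osteoblast genes 15 rose, none fell (camera adjusted p = 4.02e-10) and 3 did not pass, Atf4 and Bglap among them. Ibsp rose from 0.204 ± 0.078 to 464 ± 14 CPM (log2 fold change 11.09 ± 0.30, adjusted p = 9.97e-21), Sp7 by 4.72 ± 0.19, Omd by 3.99 ± 0.43, and Ifitm5, a membrane protein of mineralizing osteoblasts, from 0.655 ± 0.033 to 27.6 ± 3.3 CPM. Of 14 phosphate and mineralization regulators 10 rose, Fam20c and Slc20a1 fell by 0.36 ± 0.13 and 0.75 ± 0.07, and 2 did not pass. Mgp, Phex and the phosphatase Phospho1 rose by 3.88 ± 0.23, 3.75 ± 0.34 and 3.50 ± 0.42 (camera adjusted p = 0.00309, and adjusted p = 0.0528 with an estimated correlation). Slc13a5 rose by 6.14 ± 0.38 (adjusted p = 2.03e-14) and Slc13a3 by 1.47 ± 0.35. Slc25a1, Cs, Acly, Aco1 and Idh1 fell by 0.58 ± 0.13, 0.72 ± 0.07, 1.16 ± 0.13, 0.46 ± 0.08 and 0.29 ± 0.08, and the citrate list gave a camera adjusted p = 0.438 (direction down), with a median of -0.29 and a mean of 0.38, and fry, against the sign of the mean, put it on balance lower (adjusted p = 0.000101).

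Of 27 genes of extracellular vesicle biogenesis, 12 rose and 10 did not pass in the late window, and Hgs, Rab35, Tsg101, Vps4a and Vps36, which act in endosomal sorting and traffic, fell by 0.72 ± 0.08, 0.54 ± 0.08, 0.44 ± 0.13, 0.31 ± 0.08 and 0.25 ± 0.09. The annexins Anxa2 and Anxa5 and the tetraspanins Cd63 and Cd9 rose by 1.94 ± 0.15, 1.60 ± 0.11, 1.73 ± 0.15 and 1.60 ± 0.10. That list's camera adjusted p was 0.0154, and the adjusted p = 0.31 with an estimated correlation (fry adjusted p = 7.37e-08, higher). All 24 fibrillar matrix genes rose (camera adjusted p = 4.73e-18), with Postn at 976 ± 32 CPM, Aspn and Dcn up by 4.43 ± 0.23 and 3.20 ± 0.10 and the microfibril protein Mfap5 up by 5.13 ± 0.40. Of 17 cartilage genes 12 rose (camera adjusted p = 0.00013), and Sox9, Sox5 and Sox6, transcription factors that also act in neural tissue, and Col2a1 fell by 1.9 ± 0.10, 1.57 ± 0.17, 1.43 ± 0.14 and 0.38 ± 0.14. The rises included Matn1, to 75.0 ± 7.7 CPM, Acan and Cnmd, by 4.19 ± 0.20 and 3.20 ± 0.15, and Snorc, with no count at E12.5, at least 34.7-fold higher.

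In the same libraries all 16 skeletal muscle genes rose (camera adjusted p = 3.82e-11), Acta1, Myh8, Myl1 and Tnnt3 by 4.77 ± 0.30, 4.52 ± 0.19, 4.23 ± 0.37 and 4.02 ± 0.39. Of 14 epidermal genes 13 rose, all but Lor (camera adjusted p = 1.08e-11), Krt14 by 4.70 ± 0.18, Krt1 by 4.46 ± 0.23, Krt77 by 6.69 ± 0.75 and Krtdap from no count, at least 172-fold. Of 17 trunk Hox genes, which mark tissue behind the head, only 4 passed the filter on counts, and 3 of these rose (camera adjusted p = 0.00136). A gene that is high at a single stage can pass that filter, so these 4 do not stand for all 17. Hoxd8 reached 13.8 ± 2.4 CPM, Hoxd9 3.69 ± 0.39, and Hoxa5, with no count at E12.5, was at least 24.4-fold higher, while Hoxa10 had no count at either stage. All 12 neural progenitor genes fell (camera adjusted p = 6.53e-16). Among them, Sox3, Sox1 and Hes5 fell by 6.08 ± 0.20, 5.77 ± 0.14 and 4.37 ± 0.21. Of 15 neuronal genes 8 fell, Neurog2 by 6.36 ± 0.20 and Map2 by 2.27 ± 0.18, and 4 rose, Nefl by 3.35 ± 0.11 and Nefm by 2.50 ± 0.08, and the list was not shown to move relative to other genes (camera adjusted p = 0.0518, direction down, median log2 change -1.1). Its mean log2 CPM was 6.09 at E12.5, 7.05 at E13.5 and 5.32 at E14.5. Of 13 genes of the mitochondrial genome 10 rose, 11 adjusted over the list alone (camera adjusted p = 0.00399, and adjusted p = 0.244 with an estimated correlation). Of 20 proliferation genes 19 fell, all but Birc5 (camera adjusted p = 9.63e-12), and Rrm2, Mcm7, Mcm2 and Plk1 fell by 1.88 ± 0.06, 1.5 ± 0.08, 1.39 ± 0.12 and 1.30 ± 0.07. Adjusted over the list alone, 20 proliferation genes were lower, and apart from the mitochondrial genome the other lists described for this window gave the same counts.

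By size alone the late rises were Ibsp, Krtdap, Bpifa1 (at least 154-fold), the desmosomal cadherin Dsg1a (at least 149-fold), the mast cell tryptase Tpsb2 (at least 128-fold) and H60c (at least 101-fold). The falls began with Olig3, from 8.35 ± 0.49 to 0.0178 ± 0.031 CPM, Wnt8b, from 79.6 ± 3.0 to 0.321 ± 0.39, and Robo3, from 110 ± 11 to 1.03 ± 0.057. They went on with Mir9-3hg, from 172 ± 6.0 to 1.65 ± 0.34, Fezf2, from 79.5 ± 3.9 to 0.909 ± 0.14, and the cortical factor Emx1, from 85.5 ± 6.3 to 1.00 ± 0.079. In total 5070 genes were higher and 5736 lower, 46.9% higher, against 58.4% (6072 and 4333) with totals alone, which shifted the median by 0.14. With the libraries labelled E11.5 in place of E12.5, the Slc13a3 difference was -0.03 (adjusted p = 0.938) and the Aco1 difference -0.17 (adjusted p = 0.0965), and with no filter the Idh1 difference was -0.23 (adjusted p = 0.0972). Slc39a1, at 0.10 (adjusted p = 0.287), passed with DESeq2 (0.19, adjusted p = 0.0178) and with totals alone (0.24, adjusted p = 0.0131). The windows share the E10.5 and E12.5 libraries, so chance errors of adjoining windows run in opposite directions.

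Between consecutive stages, from 1699 genes (E10 to E10.5) to 13816 (E11.5 to E12) changed. The largest counts were those into and out of E12, where the lowest correlation between libraries of a stage, 0.9649, was also found. Differences of stage and of libraries cannot be told apart at these steps. The counts were 4052 from E8.5 to E9, 4577 to E9.5, 5364 to E10, 7324 from E10.5 to E11, 4613 to E11.5, 12645 from E12 to E12.5, 10650 to E13.5 and 10210 to E14.5, and the last 2 steps are longer than the others. In the early steps the largest changes included Dnm3os, which rose to 6.46 ± 1.1 CPM at E9, Ddit4, which fell from 273 ± 18 to 49.2 ± 1.2 at E9.5, and Eomes, which rose to 16.6 ± 1.4 at E10. Kdm5d, a Y-linked gene, fell from 19.3 ± 2.8 CPM at E8.5 to 0.0584 ± 0.059 at E9, where the summed Y-linked genes stood at 0.421 ± 0.16 CPM. The balance of Xist to Y-linked genes differed between stages, so sex and stage cannot be told apart for Kdm5d and Xist. Ly6a, a surface antigen of blood and vessel cells, had 34.9 ± 3.3 CPM at E9.5 and no count at E9 or E10, which were at least 570-fold and 599-fold lower. From E10 to E10.5, Xist, the RNA of the inactive X chromosome, fell from 774 ± 44 to 166 ± 13 CPM. Foxe3 rose from 1.76 ± 1.3 to 5.48 ± 0.64, a call lost without E10.5 replicate c (adjusted p = 0.0506), E10 replicate a (0.0929) or E10 replicate c (0.0774).

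In the later steps, Ttr rose to 44.1 ± 2.8 CPM at E11 while Lrtm1 fell to 1.22 ± 0.28 from 44.6 ± 2.8. Ibsp gave both the largest rise into E11.5, to 15.1 ± 0.63, and the largest fall into E12, to 0.037 ± 0.064. Cryaa, a lens crystallin, had 36.8 ± 3.1 CPM at E11, 0.0336 ± 0.058 in the libraries labelled E11.5, 21.4 ± 6.1 at E12 and no count at E12.5, at least 382-fold lower than at E12. Srrm4os rose to 8.06 ± 1.7 at E12.5, Bpifa1, with no count at E12.5, to 9.72 ± 2.0 at E13.5, and Vsig2 to 7.81 ± 0.75 at E14.5, whereas Olig3 fell to 0.094 ± 0.065 at E13.5 and Sstr3 to 0.0535 ± 0.053 at E14.5. The counts were more than 1.5 times higher at 5 steps when only the 6 libraries compared were fitted, at 7573 from E8.5 to E9, 7757 to E9.5, 8331 to E10, 5632 to E10.5 and 7720 from E11 to E11.5. From E10 to E10.5, the count was 1131 without E10.5 replicate a, 1064 without E10 replicate a and 1091 without E10 replicate c.

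**Figure D4:**
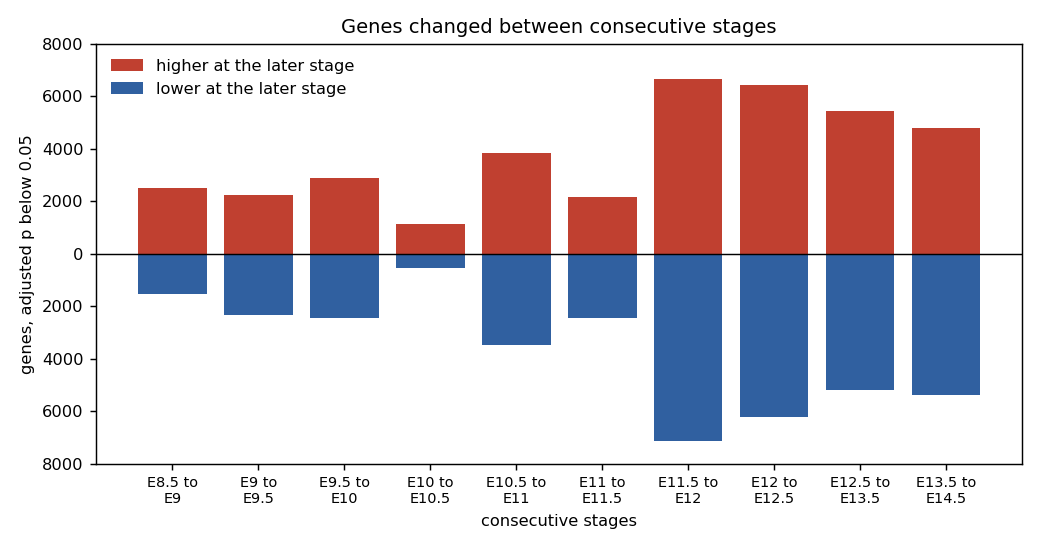
Number of genes with adjusted p below 0.05 (vertical axis) at each of the 10 steps between consecutive stages (horizontal axis), higher at the later stage above the line and lower below it. Counts were lowest from E10 to E10.5, at 1150 higher and 549 lower, and highest from E11.5 to E12, at 6675 and 7141. The E12 libraries held the pair that correlated least within a stage.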

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

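The alternatives with a length correction, with the E11.5, E12 and E13.5 libraries removed and with libraries labelled E11.5 in place of E12.5 were chosen after the data were seen. For 22 counts of genes, 362 of 381 values under the alternatives stayed within 1.5 times the count reported. For 143 differences of single genes, 2111 of 2185 kept their direction and their side of the threshold, as did 1148 of 1209 for 93 list tests, of which 35 were lost with an estimated correlation. Fits that left out 1 library gave 183, 846 and 551 of the values that stayed, and share most libraries with the main fit. A block on the column letter kept all of these results, and DESeq2 kept all 22 counts. Deviations from the stage mean correlated across stages at a median of -0.003 for the same letter and 0.001 for different letters. The letters thus did not pair libraries, and the block tested little. With totals alone, fewer genes were lower, 4265 at E14.5 than at E8.5, 2728 at E10.5 than at E8.5 and 2211 at E12.5 than at E10.5, and 6 citrate genes were higher at E14.5, where Ank reversed to 0.27. With the libraries labelled E11.5 in place of E12.5, 5595 genes were lower than at E10.5, Slc13a3 differed by 0.86 from E10.5 and by -0.03 to E14.5, and Slc13a5 by 0.42 from E10.5. Without the E11.5, E12 and E13.5 libraries the first 4 steps gave 7344, 7616, 8341 and 4765 genes. A fit of only the 6 libraries compared gave 7573, 7757, 8331 and 5632 for those steps and 7720 from E11 to E11.5. Each of these 2 fits called 5 citrate genes higher at E14.5. For the counts given, both fits left the E12 and E13.5 libraries out of the estimate of spread, which the main fit took from all 33 libraries. The cause was not tested for any of these changes. Leaving out 1 library at a time gave 1064 to 1357 genes from E10 to E10.5. In that step DESeq2 left 2728 genes without an adjusted p. Depth limits the genes with few counts, such as Slc13a5 with 9 counts at E8.5.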

Other observations

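The tests of a sex mix in E13.5 replicate c, of a tissue mix in the libraries labelled E11.5 and of Slc13a5 against other lists were chosen after the results they measure were seen. The rules that label the red cell and sex mix tests were changed after their values were seen, so that the share of the squared difference left is set aside and the Y-linked difference has to exceed the SD over all genes. By the rules first written both explanations were excluded, and by the changed rules both stay open. The length-corrected values of the sex-linked genes were also added then. In the early window, E8.5 to E10.5, genes of the response to low oxygen and of surface epithelium fell. Of 11 hypoxia genes 7 fell and Adm and Vegfa rose (camera adjusted p = 0.000528), and 8 were lower and 2 higher when adjusted over the list alone. The fall was not steady, as the mean log2 CPM of the hypoxia list was 4.71 at E8.5, 5.53 at E9 and 4.17 at E10.5. The glucose transporter Slc2a1 fell from 752 ± 13 to 266 ± 7.7 CPM, and Egln3, Pdk1 and Bnip3 fell by 1.30 ± 0.12, 1.06 ± 0.06 and 0.96 ± 0.11. Of 14 epidermal genes 8 fell and Krt1 rose (camera adjusted p = 0.000599), with the same counts when adjusted over the list alone. The desmosomal protein Dsp went from 55.8 ± 4.5 to 10 ± 1.3 CPM, and Krt5, Epcam and Grhl3 fell by 2.78 ± 0.61, 1.9 ± 0.12 and 1.79 ± 0.22. Over the whole course 7 of 9 feedback targets of FGF signalling fell (camera adjusted p = 0.00616), and Il17rd, Etv5, Spred2 and Spry1 fell by 1.44 ± 0.17, 1.42 ± 0.09, 1.32 ± 0.16 and 1.04 ± 0.11. With totals alone 7 of these 9 genes were lower and 2 higher.

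In the late window, E12.5 to E14.5, imprinted growth genes, glial genes and endothelial genes rose. Of 10 imprinted genes 7 rose and none fell (camera adjusted p = 0.000154), the long RNA H19 from 1446 ± 94 to 6240 ± 331 CPM, and Dlk1, Igf2 and Meg3 by 2.43 ± 0.11, 1.85 ± 0.29 and 1.79 ± 0.07. Of 9 glial genes 8 rose and Fabp7, which neural progenitors also express, fell (camera adjusted p = 0.000931), with Sox10 at 22.7 ± 1.9 CPM and S100b and Cdh19 up by 3.57 ± 0.32 and 2.18 ± 0.32. Of 13 endothelial genes 10 rose and none fell (camera adjusted p = 0.00101), with Cdh5, Tek, Pecam1 and Emcn up by 1.13 ± 0.16, 1.02 ± 0.09, 0.96 ± 0.10 and 0.94 ± 0.13. Adjusted over the list alone, the counts were the same for these 3 lists.

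Xist was at 573 ± 44, 1050 ± 47, 166 ± 13 and 1720 ± 120 CPM at E8.5, E9, E10.5 and E11, and 4 Y-linked genes summed to 54.1 ± 7.6, 0.421 ± 0.16, 199 ± 6.8 and 117 ± 7.3 CPM at those stages. Their sum was 32.9 ± 6.7 at E13.5 and 262 ± 19 at E14.5. The balance of sex-linked genes thus differed between stages, and sex was not part of the model. The antigen gene Ly6c1 was at 11.8 ± 0.96 CPM at E9.5, and the adult globin Hbb-bs was at 7.69 CPM at E9, 32.8 at E9.5 and 5.07 at E10.

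At most stages the balance of Xist to Y-linked genes differed little between the 3 libraries. The median SD of the log2 ratio within a stage was 0.08 and the SD between stage means 3.01, a ratio of 0.027, and without E9 the ratio was 0.047. The SD was higher at E13.5 (0.53, with 5.32, 5.28 and 4.38 in replicates a, b and c), E9 (0.51, on at most 10 Y-linked counts per library) and E12 (0.25). For the other stages this is consistent with 1 pool of embryos sequenced as 3 libraries, as a hypothesis. Separate pools of equal sex balance remain open, and no biological explanation was tested.

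The libraries labelled E11.5 lay beyond those labelled E12 and E12.5 on the first principal component and in Ibsp and Sp7, but not in Runx2 (12.6 ± 1.9 CPM, against 15.4 ± 0.67 at E12.5). A different mix of tissues alone would leave the ratio of Hbb-bh1 to Hbb-y, which both come from embryonic red cells, in stage order, but its highest value at E11.5 was 0.0144 and its lowest at E12 and E12.5 0.0545. A gene length trend alone would not leave Ibsp and Sp7 higher at E11.5 than at E12.5 by 6.13 and 1.95 on the log2 scale once it was removed. Exchanging the labels E11.5 and E12.5 changed the path through the stage means by -1.92%, the second largest shortening of 55 exchanges after that of E12 and E12.5 (-6.77%). Exchanges of E11 with E12 (-1.44%) and of E10 with E10.5 (-0.45%) also shortened it. The path uses the same log2 CPM as the first principal component, so it is not separate support. Exchanged labels remain a hypothesis. A single wrong label or embryos ahead of their nominal stage also remain open and were not tested.

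The E12 libraries, and E13.5 replicate c against a and b, differed by more than other libraries of a stage, with an SD of log2 differences across genes of 0.86 and 0.65 against 0.38 to 0.53 in 27 other pairs. More red blood cells stay open. The non-globin erythroid genes had medians of 0.11 (SD 0.66) and 0.26 (SD 0.61) against 1.54 and 1.04 for globins. These medians were not below 0.5 of the globin medians by more than that SD. The SD is the spread of single genes and not the error of a median, so the rule cannot decide. The share of the squared difference left without these genes, 99.8% and 99.9%, decides nothing with 7 globin and 9 erythroid genes among 20073. A mix with more male embryos in E13.5 replicate c would raise the summed Y-linked genes while Xist falls. The sum and Xist instead differed by -0.54 and -1.46, so this prediction was not met. A different sex mix stays open, since the differences rest on that library alone. The first was set against the spread of single genes (SD 0.65), which is not the error of a sum of genes, so that rule cannot decide. With the length trend removed, Xist differed by -0.62 and Kdm5d, Eif2s3y, Uty and Ddx3y by 0.23, 0.06, -0.52 and -0.86. Genes differed by length (rho across genes of -0.35 and -0.41, against at most 0.16 in size in the other pairs), and the length trend took away 8.2% and 13.3% of the squared difference, so a process tied to length may hold a part and the rest stays open. No biological explanation was tested.

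The hypothesis that Slc13a5 follows the osteoblast genes more closely than other late tissues was tested over the 11 stage means, in a family of 44 relations. Its Spearman rho was 0.57 with the osteoblast list (permutation p = 0.071, adjusted 0.15), 0.55 with muscle, 0.41 with liver and 0.28 with epidermis. Its Pearson r with the osteoblast list was 0.81 (permutation p = 0.0046, adjusted 0.013) and 0.11 without E13.5 and E14.5, so the relation rests on those 2 stages. Pearson r also passed with muscle (0.75, permutation p = 0.01, adjusted 0.023) and epidermis (0.69, permutation p = 0.022, adjusted 0.041), and was 0.48 with liver (permutation p = 0.13, adjusted 0.22), so it does not single out bone.

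Other splits of the libraries into groups of the same sizes were fitted for each count. For any change over the stages, 1 of 100 groupings, the real one, gave as many as 19136 genes, and the highest other gave 4663, so chance is excluded only for how these libraries were grouped. If the 3 libraries of a stage came from 1 pool, chance differences between pools or embryos are not excluded. The 4 main contrasts and the 10 steps have 10 splits each, too few for a share under 0.05. The real splits gave 14974, 9938, 7209 and 10806 genes in the main contrasts and the highest other gave 0. In the steps the real counts were 1699 to 13816 and the highest other gave 0, except 3776 from E11.5 to E12 (real 13816), 4638 from E12 to E12.5 (12645), 218 from E12.5 to E13.5 (10650) and 92 from E13.5 to E14.5 (10210).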
